A study of Rattus norvegicus with 6 samples.

How the data were processed

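Polyadenylated RNA from full-thickness esophagus of male Sprague-Dawley rats, an outbred laboratory strain, was sequenced as paired-end reads. The 6 libraries came from 6 separate animals. Of these, 3 were untreated controls and 3 had received a localized friction injury of the esophagus, and tissue from both groups was collected on day 28.

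The authors deposited whole-number counts per gene, one column per animal, with no normalization. Per the submitters' processing notes, the tools named were bcl2fastq 2.20.0.422, fastp 0.24.1, HISAT2 2.2.1, HTSeq 0.6.1 and DESeq2 1.50.2, and the genome build was Rnor_6.0. The role and order of these tools, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from near-identical gene copies or from overlapping antisense genes might therefore be split or merged in ways that cannot be traced from the counts. The file held 32623 Ensembl rat gene identifiers, of which 12126 had a count of 0 in every library. No column of another sample was present.

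The count file lists genes by Ensembl identifier and does not pair them with symbols. The reference gene table used here had 47357 genes and 0 Ensembl identifiers, so 0 of the identifiers in the file could be matched to a symbol, a position or a biotype. The 37 gene lists fixed before the data were examined (matrix, inflammation, epithelium, muscle, immune and other cell types) could not be tested for this reason, and no gene is named here by symbol. The rule for single genes had asked for those past the threshold with at least 1 CPM on average, groups that did not overlap and a symbol. It took the 12 with the largest and the 12 with the smallest change. The symbol requirement was dropped, the set is described by its ranges, and only the outermost 2 identifiers in each direction are printed. The parts of the rule that depended on symbols were not applied.

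Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 at its default settings (a minimum count of 10 and a minimum total of 15), which kept 14481 genes. These held between 99.89% and 99.92% of the counts of each library. Libraries were scaled by the trimmed mean of M-values (TMM), and injured was compared with control by edgeR's quasi-likelihood F test with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 fold changes are injured minus control. Their standard errors were computed as the absolute log2 fold change divided by the square root of F. Expression is given as CPM, the count scaled to the TMM-adjusted library size, with SD over the 3 animals. For genes with few counts in one group, the ratio of summed counts is given, scaled to the summed TMM-adjusted library sizes of the groups. It has an exact Clopper-Pearson 95% interval, which covers counting error only. Principal components used centred log2 CPM with a prior count of 2 over the 500 most variable genes.

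Total counts ranged from 14181903 to 18376578 per library. The biological coefficient of variation over all 6 libraries was 0.272, and the median standard error of a log2 fold change was 0.20. The test was checked on simulated counts drawn from the means, dispersions and library sizes of the injured and control comparison, with 200 changed genes among 14295 tested. The changed genes had at least 1 CPM on average, and both groups were given the same dispersions. The test recovered 30% of genes changed by 2-fold, 88% of those changed by 4-fold, 92% by 8-fold and 98% by 16-fold. Of its 166 calls, 12 were genes simulated without a change. Within each group the libraries differed by far more than sampling noise, with a chi-square of at least 16.8 per degree of freedom over genes, so no library was counted as a repeat of another.

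Control and injured libraries shared the replicate numbers 1 to 3, although they came from different animals. To see whether the numbers paired the libraries, each library's deviation from its group mean was correlated across genes with that of its numbered partner. The correlation was 0.37 for number 1, 0.37 for number 2 and 0.10 for number 3 (0.104 to 3 decimals). All 3 were above the limit of 0.1 set for pairing, the last by a small margin, and all 6 libraries correlated best with their own number. Deviations from a mean of 3 libraries are tied to each other, so these 6 matches are not 6 separate results. Since all 3 correlations passed the limit, the fit with the replicate number as a block is given beside the counts of calls. The pairing comes from the data, and no label describes what a number stands for.

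Alternatives were other scalings (relative log expression, upper quartile, library size alone, and scaling without the 50 most abundant genes), DESeq2 1.42.0, limma-voom 3.58.1 with and without sample weights, robust edgeR, no filter, a filter of 1 CPM in 3 libraries, an added fold limit, the replicate block and leaving out each library. These were listed before the data were examined, and 3 further alternatives were added afterwards. A fit with skeletal muscle genes as a covariate and the tests of gene lists were not run, since both need gene symbols. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.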

Results

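Gene expression was measured in the esophagus of 3 untreated rats and of 3 rats whose esophagus had been injured by friction with a 3D-printed device. All tissue was taken on day 28. The series concerns a rat model of esophageal stricture, a narrowing of the esophagus that follows scarring, and the comparison asks which transcripts differed in the injured organ. The control libraries held 17319294, 18263608 and 14181903 counts for replicates 1 to 3, and the injured libraries held 18376578, 15949379 and 16696043. Between 17381 and 17907 genes had at least 1 count in a library. The 10 most abundant genes of a library took 13.8% to 16.6% of its counts.

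Injured and control libraries separated along the first principal component, which held 60.0% of the variance of the 500 most variable genes. The injured libraries scored 21.6, 32.0 and 31.2 on it, and the controls scored -15.8, -51.9 and -17.0. The second component held 28.3% and spread the libraries within both groups. On it, control replicates 1, 2 and 3 scored 35.4, -27.3 and 10.5, and injured replicates 1, 2 and 3 scored 8.78, -21.4 and -5.96. Spearman correlations over the tested genes were 0.971 to 0.987 between injured libraries and 0.936 to 0.972 between controls, against 0.926 to 0.968 between the groups. Both lower control correlations involved control replicate 2 (0.936 with replicate 1 and 0.964 with replicate 3), which also stood apart on the first component, whereas control replicates 1 and 3 (0.972) were as alike as injured replicates 1 and 2 (0.971). The SD of log2 CPM was larger among controls in 65.1% of the tested genes, with a median of 0.25 in controls and 0.19 in injured animals. The median absolute log2 difference of a gene was 0.34 between control replicates 1 and 2, 0.28 between 1 and 3 and 0.26 between 2 and 3. Between injured libraries it was 0.19 to 0.26. By this measure control replicate 3 was no closer to replicate 1 than to replicate 2. The difference in spread between the groups was not tested, because 3 animals per group allow no permutation p under 0.1 and genes are not independent replicates.

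**Figure D1:**
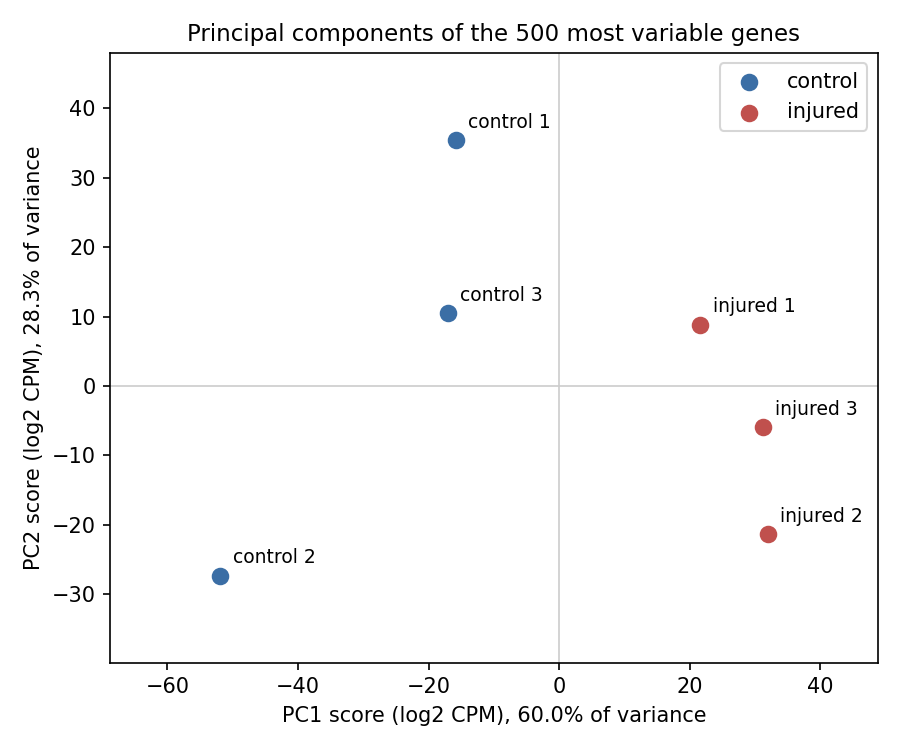
Scores of the 6 libraries on the first (horizontal) and second (vertical) principal component of log2 CPM of the 500 most variable genes, with controls in blue and injured in red. The 3 injured libraries lie between 21.6 and 32.0 on the first component and all controls lie below 0, while replicate 1 lies above replicate 2 on the second component in both groups.

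The injured esophagus had 103 genes at higher and 93 at lower transcript levels than the control esophagus, 196 of 14481 tested genes (edgeR quasi-likelihood test, adjusted p under 0.05). The genes that rose did so over a wider range than those that fell. Their median log2 fold change was 1.93, with a range from 0.54 to 10.21, while that of the genes that fell was -1.15, with a range from -5.91 to -0.55. Of the risen genes, 82 changed by at least 2-fold, 50 by at least 4-fold, 31 by at least 8-fold and 27 by at least 16-fold. Of the fallen genes, 59 changed by at least 2-fold, 18 by at least 4-fold, 7 by at least 8-fold and 2 by at least 16-fold. In all 196 genes, every injured animal lay on the same side of every control animal, which a small p at 3 against 3 makes likely. Groups that did not overlap were found in 29.2% of all tested genes. The average over all splits of 3 animals against 3 is 10%. Genes vary together, so the share in a single split can lie far from that average. This share was not counted in the other splits. At an unadjusted p under 0.05 (edgeR), 3103 genes differed, 1445 of them higher and 1658 lower in injured animals. About 724 would be expected on average with no difference at all, but with genes that vary together the count could lie far from 724.

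**Figure D2:**
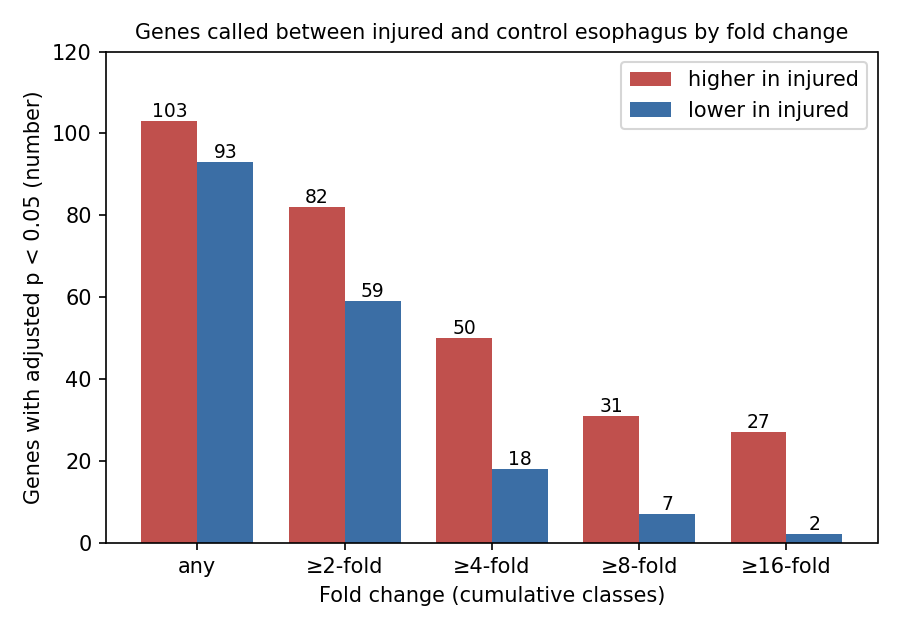
Number of genes with an adjusted p under 0.05 that were higher (red) or lower (blue) in the injured esophagus, for all calls and for those changed by at least 2-, 4-, 8- and 16-fold. Calls of at least 4-fold comprised 50 risen and 18 fallen genes.

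Fewer genes were called when any of 5 libraries was left out, which also leaves fewer animals. The total fell from 196 to 68 without control replicate 2 (34 higher and 34 lower), 12 without control replicate 3 (9 and 3), 55 without injured replicate 1 (46 and 9), 10 without injured replicate 2 (9 and 1) and 2 without injured replicate 3 (2 and 0). It rose to 334 without control replicate 1, with 134 higher and 200 lower. With the replicate number as a block, 287 genes were higher and 259 lower, and 180 of the 196 genes were among them in the same direction. DESeq2 called 756 higher and 641 lower, with all 196 genes among them in the same direction. Scaling by library size alone moved the balance to 129 higher and 67 lower, so that 65.8% of the calls were higher in injured animals, against 52.6% with TMM. The balance also moved the other way, to 40.1% higher without control replicate 1 and 41.1% with weighted limma-voom (344 higher and 494 lower), so neither direction predominated under all settings.

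The fallen genes included more abundant transcripts than the risen ones. Together the 93 fallen genes made up 20407 ± 1763 CPM in controls and 8531 ± 471 CPM in injured animals (SD, n = 3 each). The 103 risen genes made up 4049 ± 248 CPM in controls and 9899 ± 717 CPM in injured animals (SD, n = 3 each). These sums describe genes chosen for their difference and are no separate evidence for it. Ranked by mean expression over all 6 libraries, 53 of the fallen genes lay in the most abundant of 3 equal classes of tested genes (above 34.0 CPM), 27 in the middle class and 13 in the least abundant (up to 8.57 CPM). The risen genes were spread evenly, with 33, 34 and 36. Above the median abundance of 18.4 CPM there were 69 fallen and 54 risen genes, and below it 24 fallen and 49 risen genes (two-sided Fisher's exact test, p = 0.0019). That test is across genes, which are not independent replicates.

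A small group of genes was nearly silent in one group and expressed in every animal of the other. In 9 genes, each control library had at most 3 counts and each injured library at least 1 CPM, and 8 of these were called higher. The reverse was found in 1 gene, which was called lower. Among the 12 genes with the largest rise, the log2 fold change ranged from 5.37 to 10.21, and the median of the gene means was 0.10 CPM in controls and 18.4 CPM in injured animals. For 6 of these 12 genes the controls together had at most 3 counts. Among the 12 genes with the largest fall, the log2 fold change ranged from -5.91 to -2.36, and the median of the gene means was 10.2 CPM in controls and 1.20 CPM in injured animals. With the replicate block, 11 of the 12 risen and all 12 fallen genes stayed under an adjusted p of 0.05.

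The 2 largest fitted rises were in genes with almost no counts in controls, and their order differed between fits: ENSRNOG00000053703 ranked above ENSRNOG00000030187 with DESeq2, for example. ENSRNOG00000030187 rose from 0.144 ± 0.250 CPM in controls to 158 ± 149 CPM in injured animals (SD, n = 3 each). Its counts were 0, 0 and 6 in control replicates 1 to 3 and 284, 5157 and 2482 in injured replicates 1 to 3. The log2 fold change was 10.21 with a standard error of 1.61 (edgeR, adjusted p = 0.044). Scaled to library size, the summed counts differed by 1223-fold (95% counting interval 561 to 3333). This call was lost in 8 of 21 alternatives: both limma-voom fits, robust edgeR, and the fits without control replicate 1, 2 or 3 or injured replicate 2 or 3 (adjusted p from 0.058 to 0.34). ENSRNOG00000053703 rose from 0.060 ± 0.104 to 76.7 ± 66.1 CPM (SD, n = 3 each), with counts of 3, 0 and 0 in controls and 396, 2465 and 1012 in injured animals. Its log2 fold change was 10.11 with a standard error of 1.21 (edgeR, adjusted p = 0.023). Scaled to library size, the ratio of summed counts was 1195 (95% counting interval 409 to 5799). In both genes injured replicate 1 was the lowest injured library.

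The largest fall was in ENSRNOG00000012674, from 2.74 ± 0.63 CPM in controls to 0.037 ± 0.032 CPM in injured animals (SD, n = 3 each). Its counts were 45, 38 and 47 in controls and 1, 0 and 1 in injured animals. Scaled to library size, the ratio of summed counts of control to injured was 70.2 (95% counting interval 19.0 to 586). The log2 fold change was -5.91 with a standard error of 0.61 (edgeR, adjusted p = 0.020). ENSRNOG00000009345 fell from 9.62 ± 3.37 to 0.377 ± 0.169 CPM (SD, n = 3 each), with counts of 174, 224 and 82 in controls and 9, 3 and 8 in injured animals. Its log2 fold change was -4.64 with a standard error of 0.46 (edgeR, adjusted p = 0.020). ENSRNOG00000053703 lost its call in 6 of 21 alternatives, ENSRNOG00000012674 in 4 and ENSRNOG00000009345 in 3, with no change of direction. For ENSRNOG00000053703 these were both limma-voom fits and the fits without control replicate 2 or 3 or injured replicate 2 or 3 (adjusted p from 0.054 to 0.16). For ENSRNOG00000012674 they were the fits without control replicate 3 or any one injured replicate, and for ENSRNOG00000009345 those without any one injured replicate (adjusted p up to 0.13 in both).

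**Figure D3:**
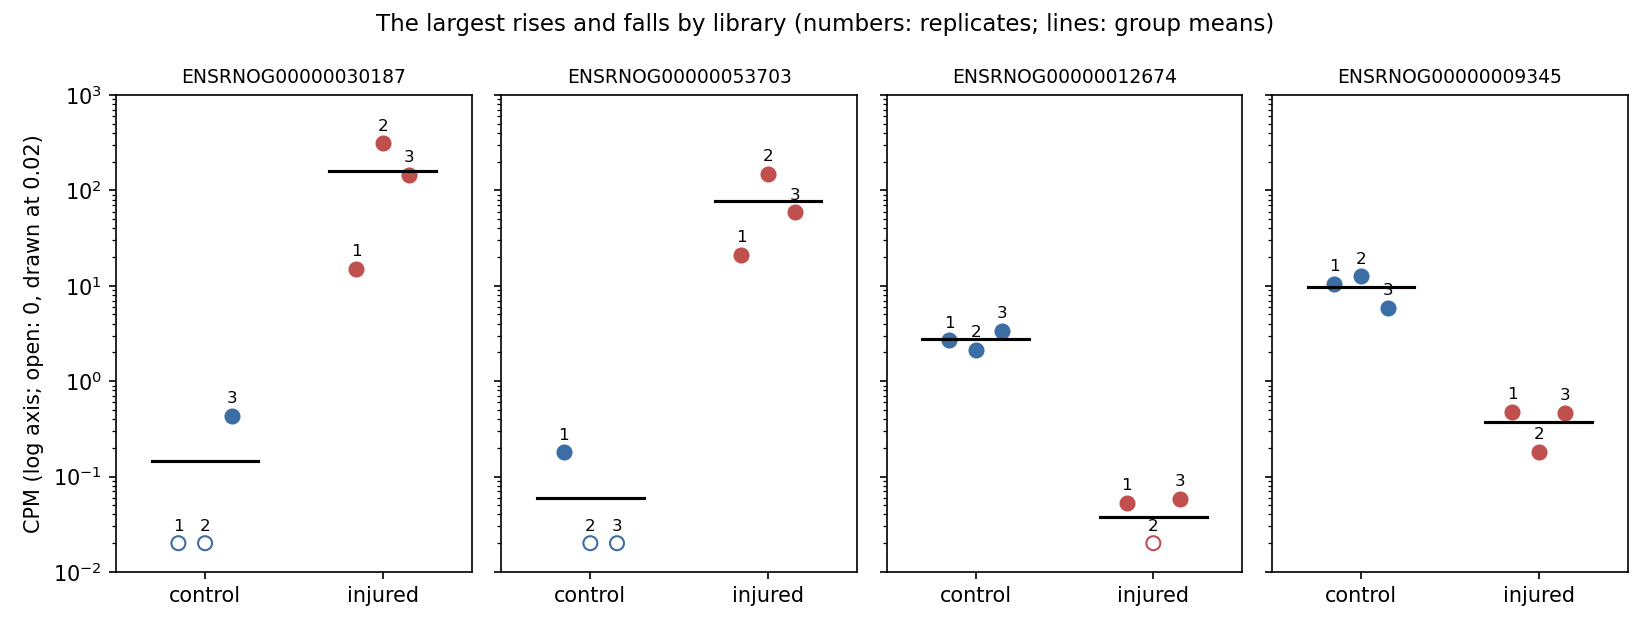
CPM (log axis) of the 2 genes with the largest rise and the 2 with the largest fall, by group; each point is a library with its replicate number, lines are group means, and open points are counts of 0 drawn at 0.02. For ENSRNOG00000030187 injured replicate 1 stands at 15.1 CPM against 313 and 145 CPM in injured replicates 2 and 3.

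Of the 12 genes with the highest total counts, none passed the test, and 1 had an unadjusted p under 0.05 (edgeR). That gene, of rank 4, stood at 16076, 18232 and 21717 CPM in controls and at 10135, 8043 and 10303 CPM in injured animals, a log2 fold change of -0.98 (edgeR, adjusted p = 0.067). It passed with the replicate block (edgeR, adjusted p = 0.039) and with DESeq2 (adjusted p = 1.63e-05), and was the only gene of these 12 that did so with either.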

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

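Of the tests in this part, those with DESeq2 on the filtered genes, DESeq2 with the replicate block, edgeR with bias-adjusted deviance and the splits of the libraries were chosen after the main result was seen. The numbers of genes called, 103 higher and 93 lower, stayed within 1.5 times under the other 4 scalings, robust edgeR, both other filters and bias-adjusted deviance (90 to 138 higher, 67 to 130 lower). DESeq2 called 756 higher and 641 lower, or 770 and 669 on the filtered genes, and limma-voom called 55 higher. With sample weights, limma-voom called 344 higher and 494 lower. A limit of 1 on the log2 fold change left 59 lower. The replicate block gave 287 higher and 259 lower, and 957 and 631 with DESeq2. Leaving out 1 library gave 2 to 134 genes higher and 0 to 200 lower, with the fewest without injured replicate 3 (1945 genes at an unadjusted p under 0.05) and the most without control replicate 1. The first principal component held 47.4% of the variance over all tested genes. The muscle covariate and the list tests were not run, for want of gene symbols. None of the 196 genes changed sign in any of these fits that tested it. The groups did not overlap in any of these genes, so a change of sign was hardly possible and its absence is no separate evidence. Except for the fold limit, which can only reduce the calls, the cause of these shifts in the number of calls was not tested. Fits without 1 library had equally few animals, so that number does not explain their spread of 2 to 334 calls. Its part in the change from 196 is untested. On simulated counts for this comparison, built from edgeR's own dispersions over 14295 genes, 54 of 225 DESeq2 calls and 12 of 166 edgeR calls were unchanged genes. In the 10 splits of the 6 libraries into 3 and 3, edgeR called 196 genes in the real split and at most 0 in another, so 1 split reached the real count. With the block, among the 4 splits that part all pairs, the real one gave 546 and the highest other 0. Both sets of splits are too few for a share under 0.05. DESeq2 called 1397 genes in the real split and at most 185 in another, which set control replicate 1 and injured replicates 1 and 3 against the rest. At this depth and number of animals, a gene changed by 2-fold was recovered in 30% of simulated cases, so a gene that was not called is not shown to be unchanged. The simulation gave both groups the same dispersions, whereas the biological coefficient of variation was 0.33 within controls and 0.20 within injured animals. The share recovered need not hold for the real data.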

Other observations

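Of the tests in this part, those of a shared batch and of uninjured tissue in genes chosen without injured replicate 1 were chosen after the result was seen, as was the comparison of replicates 1 and 2. Beside the difference between the groups, a set of abundant transcripts varied strongly among animals of the same group. Of 1599 genes with a mean of at least 100 CPM, 198 spanned more than 2-fold among the controls and 74 among the injured animals. In 54 of these 1599 genes replicate 1 stood at least 2-fold above replicate 2 in both groups, in 4 it stood at least 2-fold below in both groups, and in 1 the groups went opposite ways. The genes of abundance rank 5 and 6 are examples. The gene of rank 5 stood at 19502, 2835 and 9814 CPM in control replicates 1 to 3 and at 20617, 8429 and 18755 CPM in injured replicates 1 to 3. The gene of rank 6 followed it, with a ratio between the genes of 1.03 to 1.26 over the 6 libraries.

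Same-numbered control and injured libraries deviated from their group means together, with correlations across genes of 0.37, 0.37 and 0.10 for numbers 1, 2 and 3. The tables argue against a difference in library size, since thinning every library to 14181903 counts left the lower of the first 2 correlations at 0.356. Nor did the first 2 correlations rest on the 500 most abundant genes: without them the lower was 0.354. The third fell to 0.0997, just under the limit of 0.1 set for pairing. Every gene weighs the same here, so leaving out 500 of 14481 could change little. This does not decide whether a few genes taking most of the counts played a part. A batch shared by same-numbered libraries stays open. Matching by number had the highest summed correlation (0.83) of the 6 possible matchings, rank 1, with 0.34 for the next, but 6 matchings cannot give a share under 0.05, and differences in the tissue sampled from each animal may give the same picture and were not tested without gene names.

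Injured replicate 1 lay below the other injured libraries in the genes that rose most. In the 31 genes called at least 8-fold higher, the median log2 difference of each injured library from the mean of the other 2 was -0.94, 0.90 and 0.22 for replicates 1 to 3. Replicate 2 lay above the others about as far as replicate 1 lay below them. The values therefore do not tell a low replicate 1 from a high replicate 2. Genes vary together and are not independent replicates, so these values carry no spread between animals. A larger share of uninjured tissue in replicate 1 stays open. In the 93 fallen genes replicate 1 stood 0.016 above the others (interval over genes -0.057 to 0.077). That is far below the 0.63 that the needed share of 47.7% would give. But those genes were called with that library included, which favours genes where the injured libraries are alike. The fit without replicate 1 had 151 genes at least 2-fold lower (edgeR, unadjusted p under 0.01). In these, replicate 1 stood 0.31 above the others (interval over genes 0.18 to 0.51). That is the direction mixing predicts, although genes chosen without a library tend to look weaker in it. The value lies below the 1.31 that would match the 97 genes at least 8-fold higher in that fit, at a needed share of 69.7%. A difference shared with control replicate 1 also stays open: in the 73 risen genes with at least 1 CPM in controls that library differed from the other controls by a median of 0.0019, but most of these genes lie outside the 31 that show the pattern, so the value decides nothing, and a weaker response in this animal is a candidate explanation that the design cannot test.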
